A study of Mus musculus with 12 samples.

How the data were processed

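Gene expression, hashtag and T cell receptor libraries were made from 4 lanes of a pool of hashtagged, sorted CD4 T cells, with a 5′ single-cell kit per the series' design text. Cell Ranger 7.1.0, R 4.4.2, Seurat 5.1.0 and the genome build mm10 are named in the submitters' processing notes, without their roles or settings. The annotation and the cell-calling settings are not given in the sources used here. The deposited files used here hold text and no measured level. The first, as deposited by the authors, lists 1 cell barcode per line, a sequence of 16 bases followed by a number from 1 to 4, and its name says that it was filtered. The second lists the identifier, name and kind of each quantified feature. The third, per the file header, gives the identifier, name, read, position pattern and sequence of each hashtag. The count matrix, hashtag reads per cell and receptor contigs were not analysed here. For that reason the planned test of expression by housing and antibody was not run, depth per cell is unknown, and no cell filter, doublet call or clustering was applied. Columns of per-sample values left unused numbered 0.

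The libraries were grouped by their kind (gene expression, hashtag or receptor) from their titles, with the lane as replicate. No label ties the number at the end of a barcode to a lane number, so lanes are named by that number. The gene expression library of lane 1 alone carries a batch value in its labels, whose meaning is not given in the sources used here, and it was not used. The labels put no library in a housing or antibody group, since by the design text the sorted cells were pooled, and the groups of the hashtags were read from the hashtag names. A hashtag is taken to stand for a mouse because the labels describe the tagged samples as biological replicates. The number of cells loaded per lane was taken from the design text.

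Barcodes per lane were compared with a chi-square test of equal numbers, and each lane's share of the loaded cells was given a 95% Wilson interval. For every pair of lanes the number of shared sequences was compared with the product of the lanes' barcode numbers divided by a pool size, estimated from all 6 pairs together. A chi-square test asked whether the pairs have a common pool size, and overlaps of 3 and 4 lanes were predicted from that size, with exact Poisson intervals. Pairs of barcodes differing at 1 base were counted within and between lanes, per possible pair, with an exact binomial interval for the ratio. The base composition at each of the 16 positions was compared over lanes with chi-square tests and Benjamini-Hochberg adjustment. All thresholds for p-values were 0.05. Ratios set against crossing or split cells were read by bounds on their 95% intervals or on the excess these allow. For pairs at 2 bases the interval had to include 1 and lie below 1.2. Computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and plots matplotlib 3.10.9.

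The estimate of pool size was tested on simulated data, in 20 draws of 4 lanes of the observed sizes from a known pool. The estimate lay between 0.976 and 1.03 times the true size, and 0 of the 20 draws gave p under 0.05 in the test of a common pool size. With 2% of the barcodes of 1 lane copied into 1 other lane, that test gave a chi-square p of 1.50e-30. Crossing spread alike over all lanes was not simulated. It would lower the pool size of every pair and need not show in that test. In each lane, 100 further barcodes were planted, each differing at 2 bases from a real barcode of that lane. The ratio of rates within and between lanes was then 1.03, with a lower bound of 1.01. The planted sequences were not limited to those that the barcode set can hold. The ratio therefore shows that the count responds, and not that real splits would be found.

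Lists of genes for T cell subsets, states and possible carry-over cells, 18 in all, were fixed before the data were examined, and members were looked up by exact symbol. The rule for named genes, fixed at the same time, was to name every list, every missing member, every feature that is not an ordinary gene, and the opening 4 members of each list. Some of these members are not reported here. Zfp683, Iltifb, Flicr, Tcrg-C3, Defa24, Il2, Lyz1, Trbc1 and Trbc2 were named after their values were seen. Coordinates come from GENCODE M21 on GRCm38, matched by gene identifier. For 733 of the matched identifiers the name in the feature table differs from the name in GENCODE M21. Among the feature names, 38 symbols stood on more than 1 identifier, and none of them was in the lists. For each list member, the share of its different 50-base transcript sequences that also occur on the same strand in a transcript of another listed gene was computed from the GENCODE M21 transcripts, with 90 bases as a second length. The read length is not given in the sources used here. Whole transcripts were searched, without regard to which part of them the 5′ libraries read.

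Alternatives tried were leaving out each lane, using only sequences found in 1 lane, leaving out barcodes with a neighbour at 1 base, taking the median of the pool sizes of single pairs, a distance of 2 bases in place of 1, symbols compared without regard to case, and hashtag distances with a shift of 1 base. The pool size from the parts of the barcode was added after seeing the data. Lanes of a pool are technical splits, and the tests on them take counting error as their only source of spread. Their p-values therefore do not measure the spread between mice.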

Results

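The series measured CD4 T cells of the lamina propria of the mouse small intestine by droplet-based single-cell sequencing from the 5′ end of the transcript. The mice carried a T-bet-ZsGreen reporter, a green fluorescent protein that marks expression of T-bet, the transcription factor of type 1 immunity encoded by Tbx21. They were housed either specific pathogen-free (SPF) or germ-free (GF), and received either an antibody against CD3 (anti-CD3), which engages the T cell receptor complex, or an isotype control antibody. The cells of each sample were tagged with a hashtag antibody, an antibody that carries a DNA tag, then sorted, pooled and loaded on 4 lanes. Each lane gave 1 gene expression, 1 hashtag and 1 T cell receptor library, which makes 12 libraries. The series title places the study in type 1 regulatory T (Tr1) cells, T cells that make interleukin-10 without depending on FOXP3, and in dietary signals that act on them. The data described here are the list of cell barcodes, the table of quantified features and the table of hashtags. Count levels, hashtag reads per cell and receptor sequences were not analysed here, so no gene, clonotype or cell type is compared between SPF and GF mice or between anti-CD3 and isotype.

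The hashtags name a crossed design of housing and antibody with 15 members. The SPF isotype group had 4 hashtags, the SPF anti-CD3 group had 3, the GF isotype group had 4 and the GF anti-CD3 group had 4. Members were numbered 1 to 3 in the SPF anti-CD3 group and 1 to 4 in the others, and whether the study held a further SPF anti-CD3 member is not known here. All 15 were listed under the same identifiers and names in the hashtag table and in the feature table. A comparison of housing under the isotype antibody therefore sets 4 hashtags against 4, and so does a comparison of anti-CD3 with isotype in GF mice. An exact two-sided permutation test of such a comparison can reach a p of 0.0286 at the lowest, over 70 splits. A comparison of anti-CD3 with isotype in SPF mice, or of SPF with GF mice under anti-CD3, sets 3 hashtags against 4. The smallest exact two-sided permutation p for 3 against 4, over 35 splits, is 0.0571 where the smaller tail is doubled and 0.0286 where the absolute difference of means is counted. By the design text, sorted cells were pooled before loading, so a lane is treated here as a technical split of the pool and not as a mouse or a treatment. The files used hold no hashtag reads per cell, so which groups each lane held was not checked.

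Each hashtag was a sequence of 15 bases, of which 6 to 8 were G or C. Over the 105 pairs of hashtags the number of differing bases had a median of 11 and a range of 6 to 15. The closest pair joined 2 different groups. It was the hashtag of the GF anti-CD3 member numbered 4, GATGTATCCGTTGTC, and that of the GF isotype member numbered 1, CAAGTATCTGCCGTG, which differed at 6 bases. The next closest pair, the SPF anti-CD3 member numbered 2 and the SPF isotype member numbered 3, differed at 7 bases.

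The feature table held 32285 genes and the 15 hashtags. Of the gene identifiers, 32235 (99.8%) were found in the GENCODE M21 annotation of the mouse genome build GRCm38, the assembly that mm10 denotes, and 50 were not. By that annotation 21702 of the genes were protein-coding and 9830 belonged to long non-coding classes. A further 270 were T cell receptor segments and 427 were immunoglobulin segments, pseudogenes included. By name the receptor segments comprised 128 Trav, 60 Traj, 35 Trbv and 14 Trbj genes of the alpha and beta chains. There were 6 Trdv genes of the delta chain and 4 constant genes of the gamma chain. The table listed 0 features with ZsGreen in their name, so T-bet is represented by Tbx21 and not by the reporter transcript.

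The Tr1 list stood in the feature table in full, with 20 of 20 members listed. Its opening members are Il10, the gene of the suppressive cytokine interleukin-10, Lag3 and Havcr2, which encode inhibitory receptors, and Itga2, which encodes the integrin CD49b. Il10 (ENSMUSG00000016529) lies on chromosome 1 from 131019845 to 131024974 on the plus strand. Lag3 (ENSMUSG00000030124) lies on chromosome 6 from 124904361 to 124911705 on the minus strand. Itga2 (ENSMUSG00000015533) lies on chromosome 13 from 114833081 to 114932100 on the minus strand. Havcr2 (ENSMUSG00000020399) lies on chromosome 11 from 46454935 to 46481255 on the plus strand. Tbx21 (ENSMUSG00000001444), which belongs to the Tr1 and T helper 1 lists, lies on the same chromosome from 97098071 to 97115331 on the minus strand. These coordinates are whole protein-coding genes, exons and introns together, in GRCm38 as GENCODE M21 gives them.

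The other helper and regulatory lists were also complete in the feature table. The T helper 1 list had 12 of 12 members, opening with Tbx21, Ifng, Cxcr3 and Il12rb2. Ifng (ENSMUSG00000055170), the gene of interferon-gamma, lies on chromosome 10 from 118441046 to 118445892. The T helper 17 list had 10 of 10 members, among them Il17a, Il17f and Il22. Il22, the gene of interleukin-22, shares 41.0% of its 50-base transcript sequences with other listed genes, with its near-copy Iltifb sharing the most; at 90 bases the share was 24.1%. The regulatory T cell list had 12 of 12 members, opening with Foxp3, Il2ra, Ctla4 and Ikzf2. Foxp3 (ENSMUSG00000039521), the defining transcription factor of these cells, lies on chromosome X from 7573644 to 7595245, and it shares 14.7% of its 50-base sequences with other listed genes, with Flicr sharing the most. The follicular helper list had 9 of 9 members, opening with Bcl6, Cxcr5, Pdcd1 and Icos. The T helper 2 list had 8 of 8 members, opening with Gata3, Il4, Il5 and Il13.

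Lists of T cell state were complete except for 1 symbol. The naive or central memory list had 8 of 8 members, among them Ccr7, Lef1 and Tcf7. The list of genes induced by T cell receptor stimulation, the signal that an antibody against CD3 engages, had 12 of 12 members, opening with Nr4a1, Nr4a2, Nr4a3 and Egr1. The proliferation list had 10 of 10 members, opening with Mki67, Top2a, Pcna and Mcm2. The cytotoxicity list had 9 of 9 members, opening with Gzma, Gzmb, Gzmk and Prf1. The tissue residency list had 9 of 10 members, opening with Itgae, Itga1, Cd69 and Cxcr6. Its missing symbol was Znf683, the human spelling of the gene of the residency factor Hobit. The mouse spelling Zfp683 (ENSMUSG00000049410) was listed.

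Genes that mark the sorted cells and cells that a CD4 gate could carry over were all listed. The T cell identity list had 10 of 10 members, opening with Cd3e, Cd3d, Cd3g and Cd4. Within it, Trbc1 and Trbc2, the constant genes of the receptor beta chain, shared 40.5% and 44.0% of their 50-base sequences with other listed genes, and each shared the most with the other. The CD8 T cell list had 2 of 2 members, Cd8a and Cd8b1. The gamma delta T cell list had 5 of 5 members, opening with Trdc, Tcrg-C1, Tcrg-C2 and Tcrg-C4. Tcrg-C1 shared 34.2% of its 50-base sequences with other genes and Tcrg-C2 shared 25.4%, and for both the gene sharing the most was Tcrg-C3. With sequences of 90 bases these shares were 11.1% and 2.55%. The B and plasma cell list had 8 of 8 members, among them Cd79a, Cd79b and Ms4a1. The myeloid list had 10 of 10 members, opening with Lyz2, Cd14, Csf1r and Itgax. The epithelium list had 12 of 12 members, opening with Epcam, Krt8, Krt20 and Fabp1. The natural killer and innate lymphoid list had 7 of 7 members, opening with Ncr1, Klrb1c, Klre1 and Eomes. In total the 18 lists held 163 different symbols, of which 162 were listed, each on 1 identifier. Being listed says that a gene was among those set to be counted. It says nothing of its level or of whether any read fell on it.

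The 4 lanes together held 74799 cell barcodes, which is 46.7% of the 160000 cells loaded. Barcodes ending in 1 numbered 17900, or 44.8% of the 40000 cells loaded on a lane (95% Wilson interval 44.3 to 45.2%). Those ending in 2 numbered 19942, or 49.9% (49.4 to 50.3%). Those ending in 3 numbered 17831, or 44.6% (44.1 to 45.1%), and those ending in 4 numbered 19126, or 47.8% (47.3 to 48.3%). The mean was 18700 ± 1020 per lane (SD, n = 4 lanes), a coefficient of variation of 5.45% against the 0.731% that counting error alone gives. The highest lane held 1.12 times the barcodes of the lowest. A chi-square test of equal numbers gave p = 6.23e-36 (chi-square 167, 3 degrees of freedom), so the lanes differed by more than counting error. The intervals and the test cover counting error only. A barcode counts a droplet that was called a cell, and droplets with several cells or with cell debris were not told apart here.

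**Figure D1:**
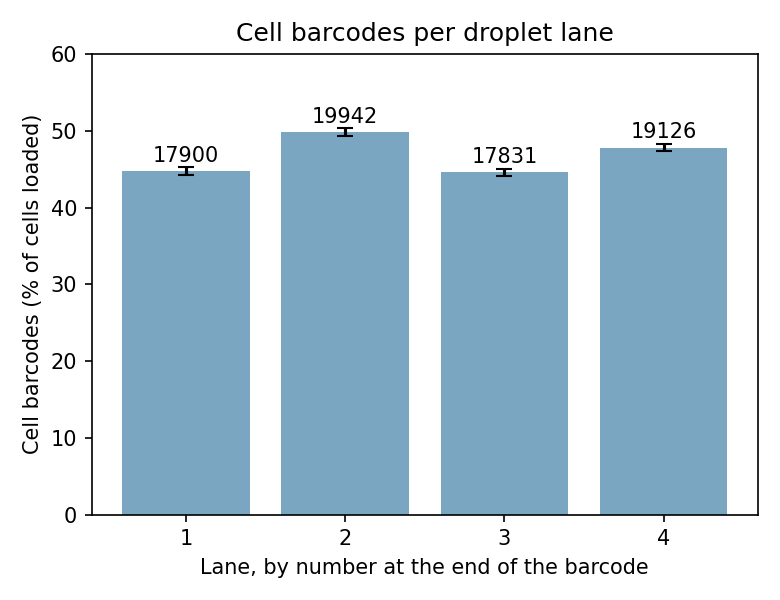
Cell barcodes of each droplet lane as a percentage of the 40000 cells loaded (vertical axis), by the number at the end of the barcode (horizontal axis). Bars are single lanes, error bars are 95% Wilson intervals and the numbers printed on the bars count barcodes, from 17831 to 19942.

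The number at the end of a barcode is needed to tell cells apart, because lanes drew on a common set of sequences. The 74799 barcodes held 71933 different sequences. Of these, 69111 occurred in 1 lane, 2781 in 2 lanes, 38 in 3 lanes and 3 in all 4 lanes. Sequences found in more than 1 lane made up 3.92% of all different sequences. The number shared by a pair of lanes ran from 436 for the lanes ending in 1 and 3 to 569 for the lanes ending in 2 and 4. Independent draws from a common pool of 719713 equally frequent sequences (95% interval 694042 to 746581, from all 6 pairs) predicted 443 and 530 for these pairs. A chi-square test did not detect a difference in pool size between the 6 pairs (p = 0.485). Sequences common to 3 lanes, counted over every choice of 3 lanes, numbered 50 against 50.4 predicted. Both numbers count a sequence of all 4 lanes once for every choice of 3 lanes. The 50 therefore holds the 3 sequences of all 4 lanes several times over, beside the 38 in exactly 3 lanes. Its closeness to the prediction is not separate from the count for all 4 lanes. Sequences in all 4 lanes numbered 3 against 0.327 predicted, with an exact Poisson upper-tail p of 0.00455 and 0.0137 after Bonferroni adjustment over the 3 kinds of overlap.

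**Figure D2:**
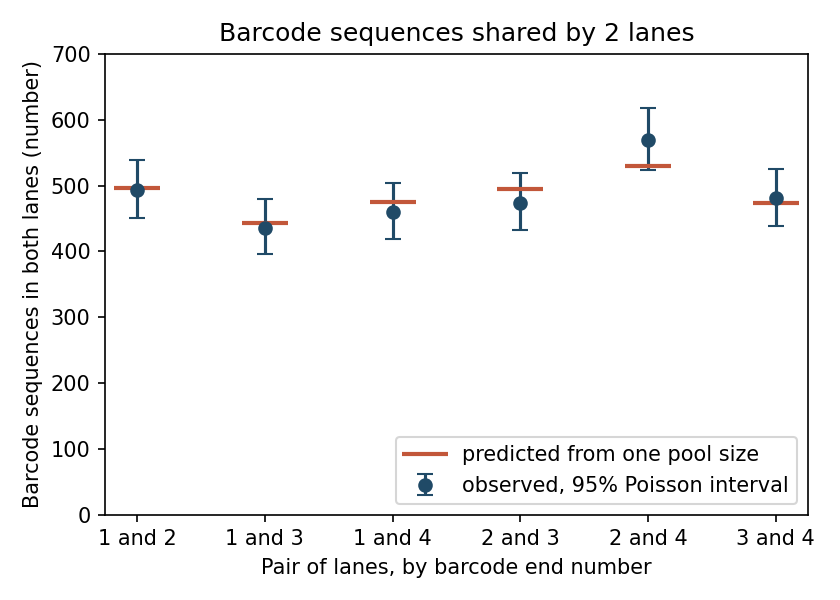
Number of barcode sequences found in both lanes of a pair (vertical axis) for the 6 pairs of lanes (horizontal axis). Points are observed numbers with 95% Poisson intervals and dashes are the numbers predicted from a pool of 719713 sequences; each prediction lies inside the interval of its pair, the pair of lanes ending in 2 and 4 (569 observed, 530 predicted) included.

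No 2 barcodes of a lane differed at only 1 base. There were 0 such pairs among 700883501 possible pairs within lanes and 0 among 2096524300 between lanes. The planned ratio of these rates could therefore not be formed. Pairs between lanes cannot come from a split cell, so their absence shows that the listed sequences hold no such neighbours whatever the lane. The count of 0 within lanes thus gives no rate of base errors. It does show that no cell was split over 2 listed barcodes that differ at 1 base. The base composition of the barcodes was compared over lanes at each of the 16 positions. With a chi-square test per position, 0 positions passed an adjusted p of 0.05 (Benjamini-Hochberg) and 1 position, the first base, passed an unadjusted p of 0.05 (p = 0.0170, adjusted p = 0.273). At that position C made up 30.4% of the barcodes, with lanes between 29.6 and 30.8%.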

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

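The ratio of the highest to the lowest number of barcodes per lane kept its side of the threshold under every alternative run, with values from 1.07 to 1.12 on leaving out each lane. The pool size behind shared sequences ran from 707370 to 735369 on leaving out each lane, and the test of a common pool size passed the threshold under none of these. The pool size was 728056 as the median of single pairs and 736800 from the parts of the barcode, the last chosen after seeing the data. A chi-square test of the pairs against each of these fixed sizes, a different test, gave p = 0.557 and p = 0.404. Counting pairs of barcodes that differ at 2 bases in place of 1 raised the number of pairs within lanes from 0 to 13198, which follows from the wider distance. The number of positions whose base composition differed between lanes was 0 under every alternative run, with the lowest adjusted p between 0.0998 and 0.821 on leaving out each lane. Ignoring case left 162 symbols listed, and a shift of 1 base left 6 as the lowest number of differing bases between hashtags. Leaving out barcodes with a neighbour at 1 base removed none, so it says nothing about stability. No paired analysis was possible because the 3 kinds of library share lane numbers but the files used here hold values for the lanes only once, and no test compares kinds of library. The test of expression by housing and antibody was not run, and without reads per cell the depth of the cells is unknown.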

Other observations

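The tests on pairs at 2 bases and on shared barcode ends were set before their results were seen, and the tests that use the parts of the barcode were chosen only after the result was seen. The test of equal numbers per lane was planned, and what it would say of counting error was written after its result. Sequence shared between genes was counted over whole transcripts, while the libraries were read from the 5′ end. The shares of the markers below therefore do not tell whether the part that was read is shared. Of 162 list members searched in the GENCODE M21 transcripts, 112 shared no 50-base sequence with another listed gene and 6 shared over 20%. These 6 were Trbc2, Il22, Trbc1, Tcrg-C1, Defa24, a Paneth cell defensin, and Tcrg-C2. At 90 bases, 3 genes stayed over 20%, with Trbc2 at 33.7%, Trbc1 at 30.9% and Il22 at 24.1%, while Tcrg-C1 was at 11.1%, Tcrg-C2 at 2.55% and Defa24 at 0%. Lyz2, the lysozyme gene used to mark myeloid cells, shared 15.4% of its 50-base sequences, its paralog Lyz1 sharing the most, and 3.59% at 90 bases. Il2 shared 12.6% and Foxp3 14.7%, against 0.825% for Lag3.

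If cells were spread evenly over the 15 hashtags listed, each would hold 4987 barcodes on average. Under the same assumption, 6.67% of random pairs of cells would carry the same hashtag, and a droplet with such a pair would not stand out by its hashtags. A further 18.7% would carry different hashtags of the same group. These values are arithmetic on the design, not measured cell numbers.

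The barcodes were built from parts. In 74799 of 74799 barcodes the base at position 8 determined the base at position 9, with 2.00 bits of mutual information between them. The next highest pair of positions, 2 and 3, had 0.0397 bits. Only 480 different sequences occurred in the first 7 bases, of 16384 possible, and 1535 in the last 8 bases, of 65536 possible. The last parts numbered 384 for each of the opening bases A, G and T and 383 for C. The product of 480 and 1535 gives a pool of 736800 sequences, inside the interval that the overlap of lanes gave without use of the parts. The composition tests at positions 8 and 9 are therefore the same test. The parts that occurred were used about evenly as a whole. Their variance over mean was 0.991 for first parts (chi-square p = 0.550) and 0.989 for last parts (chi-square p = 0.616). A part without any barcode is left out of these tests and of the pool. One last part stood far below the rest, CGTGTAGT, with 7 barcodes against 28 for the next lowest and a mean of 48.7.

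Sequences that occur in more than 1 lane could come from reads crossing between lanes or from independent draws. Over the 6 pairs, 2913 shared sequences were observed, 1.02 times the 2845 that draws from the 736800 sequences predict (95% Poisson interval 0.987 to 1.06). This argues against crossing as the source of the shared sequences. The upper bound leaves room for an excess of up to 175 barcodes, 0.234% of all. For the 3 sequences in all 4 lanes, equal draws from this pool predict 0.304 (exact Poisson p = 0.00375, 0.0112 after Bonferroni adjustment over 3 kinds of overlap), and the measured use of the parts leaves 0.303 (exact Poisson p = 0.00371). Neither prediction reaches the 3 observed. Both were made after that count was seen and lie close to the 0.327 predicted from the overlap of lanes, so they are no independent test. The excess rests on 3 sequences, and no biological explanation was tested.

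A second hypothesis was that single cells were split over several barcodes, by base errors or by beads carrying mixed barcodes, which could inflate the number of cells. Such pairs would be more frequent within lanes than between lanes. Pairs differing at 2 bases were 1.00 times as frequent within lanes as between them (95% exact binomial interval 0.985 to 1.02), with 13198 pairs within and 39309 between lanes. The upper bound leaves room for 314 excess pairs, 0.419% of the number of barcodes. Pairs with the same first part of 7 bases gave a ratio of 0.998 (0.997 to 1.00) and pairs with the same last part of 8 bases gave 1.00 (0.997 to 1.00), with room for excess pairs of up to 0.701% and 2.07% of the number of barcodes. The planned ratios were 1.00 (0.995 to 1.01) for the same first 10 bases and 0.996 (0.989 to 1.00) for the same last 10 bases. Of the pairs between lanes that share a part, 6.23% match over the first 10 bases and 25.0% over the last 10. If pairs from mixed beads match as often, the planned ratios leave room for excess pairs of up to 19.4% and 1.56% of the number of barcodes, so the first 10 bases alone set a loose limit. The intervals, and the limits drawn from them, treat pairs as independent, although each barcode belongs to many pairs. Under that assumption these ratios together argue against beads mixed on a shared part beyond the limits given. Splitting over unrelated barcodes would not show in these tests. At 1 base, 0 pairs of listed barcodes occurred within lanes, so no cell was split over 2 listed barcodes at that distance. The pairs were absent between lanes too, so how often base errors arose is not measured. A base error that gives a sequence outside the observed parts adds no listed barcode. For errors at 1 or 2 bases these values argue against an inflated number of listed barcodes, beyond the limit given for 2 bases. Errors at more bases were not tested on their own.

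The lanes differed in barcode number by more than counting error (chi-square p = 6.23e-36), although by the design text they were loaded from a common pool with the same number of cells. The labels give a batch value to the gene expression library of lane 1 alone, without its meaning, and do not say which barcode number is that lane. By Dixon's test no lane stood apart, with a gap over range of 0.387 for barcode number, below the 95% critical value for 4 samples. Loading, capture, cell calling and any batch difference each bear on this number, and none was tested.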
